A study of Mus musculus with 5 samples.

How the data were processed

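Single-cell RNA profiles were made by Drop-seq, a droplet method that captures polyadenylated RNA of single cells on barcoded beads and tags each captured molecule with a unique molecular identifier (UMI). The cells came from the colon mesenchyme of untreated mice aged 10 weeks on the C57/BL6 background. Per the labels' protocols, the epithelium was depleted with EDTA and DTT before the mesenchymal cells were released with Collagenase XI and Dispase, so the share of epithelial cells was set in part by the preparation. The 5 samples were droplet collections. Collections 1A and 1B came from biological replicate 1 and collections 2A, 2B and 2C from biological replicate 2, which left 2 biological replicates of 1 group and no contrast between conditions. The labels do not say how many animals made up a replicate.

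The deposited files hold whole-number UMI counts per gene and cell barcode, without normalisation. Reads were aligned with STAR 2.6 to mm10, per the submitters' processing notes. The counting program, the gene annotation and the rule that chose the deposited barcodes were not given in the sources used here. Gene symbols were used as the tables list them, some in an older form (Ctgf for Ccn2). All 207 genes of the tested lists that were in the tables matched a gene of GENCODE M21 on GRCm38, the assembly also called mm10. Of these, 113 overlapped another annotated gene. How the authors counted such overlaps was not stated, so reads of overlapping genes could not be told apart.

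All 7935 barcodes were read and 5985 were retained. Barcodes with under 300 genes (1263) or with more than 10% mitochondrial UMIs (667) were left out. Scrublet, run per collection through scanpy 1.11.5 with an expected rate of 0.05, marked 20 of 6005 barcodes (0.333%). That is below the 0.5% under which a doublet caller is taken not to have worked, so doublets remained among the retained cells although the 20 marked barcodes were left out. An alternative that removed the 5% of cells with the highest doublet scores in each collection was therefore added after seeing the data. Counts were scaled to 10000 UMIs per cell, logged, reduced to 30 principal components of 2000 variable genes and clustered with the Leiden method on 15 neighbours, at resolution 1.0 for all cells and 0.5 for the fibroblast-like cells alone. The 12 tested gene lists (223 signalling and lineage genes) were kept out of the clustering. The immediate-early, heat-shock and proliferation genes were described only and were not kept out of it. Clusters were named "like" a cell class from marker genes written down before the data were examined, where at least 3 markers of the class were raised and the leading genes did not go against the name. There was no deposited cell annotation among the data used here, so cluster names were rebuilt.

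UMI counts were summed per biological replicate and cell class, for classes with at least 20 cells in each replicate, and per biological replicate and fibroblast cluster. The sums of a class held 73009 to 2356285 UMIs and those of a fibroblast cluster 135744 to 1077805. The sums were compared with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, quasi-likelihood F test, two-sided), with the biological replicate as a block because sums with the same replicate number came from the same cell suspension. The gene filter kept genes that reached a minimum level in at least 2 sums, so a gene could pass through a single class or cluster. For such a gene, a higher call there was in part set by the filter. Each class or cluster was set against the mean of the log levels of the other classes or clusters. The Benjamini-Hochberg method adjusted p over all genes tested (6925 for classes and 7827 for fibroblast clusters), and the threshold was 0.05. All adjusted p-values of single genes below come from this edgeR test. Because the reference is a mean of logs, a gene could be above it in more than 1 class. For that reason, levels are given as CPM (the count of a gene scaled by the total UMIs of its sum, mean ± SD of the 2 biological replicates) for many genes with the next highest class or cluster. Fitted log2 fold changes are given ± SE, and only where every other class or cluster had at least 1 UMI. Clusters and tests used the same cells, so p-values between clusters are smaller than in independent cells. One alternative split the UMIs of each cell at random into 2 parts, of which 1 gave the clusters and the other the sums.

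Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, over lists with at least 3 tested genes. The R-spondins had fewer tested genes and no list test. Members that passed the gene filter through a single class or cluster lean the list tests, and the counts of higher members, towards it. Gene lists, cell type markers, tests, the rule for naming genes and all alternatives other than the 2 added ones (the doublet scores, and no limit on mitochondrial UMIs) were fixed before the data were examined. Among the list genes of each comparison, the rule names up to 15 with the largest positive and up to 8 with the largest negative log2 fold change of those past the threshold with the same sign in each biological replicate. For fibroblast clusters it adds 16 fixed niche and lineage genes, whatever their result. Marker genes are named only as what defines a cluster.

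The test was checked on simulated counts in which 200 genes had known fold changes. Apart from these genes, all simulated sums shared the same mean profile. They held no class differences, no replicate effect and no clusters drawn from the tested cells, so the error rates apply to such counts only. Recovery was counted over the changed genes that passed the gene filter. For the fibroblast-like class, in a step over 5116 genes, 98.81% of 84 genes with a 2-fold change and 100% of 87 with a 4-fold change were recovered. Of the calls, 3.955% were false. For fibroblast cluster 2, in a step over 7300 genes, 60% of 90 genes with a 2-fold change and 88.04% of 92 with a 4-fold change were recovered. Of the calls, 2.878% were false. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Alternatives changed the minimum of genes per cell (200 or 500), the mitochondrial limit (20% or none), the removal of doublets, the Leiden resolution, the genes used for clustering, a correction for collection (ComBat), the normalisation (RLE factors, or DESeq2 1.42.0 with its own size factors), the gene filter, the replicate block, sums per collection, and the list test. Each collection was also left out in turn. Leaving out a biological replicate gave fold changes only, because 1 replicate leaves no spread to test against.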

Results

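The cells of the colon mesenchyme of untreated adult mice were profiled by Drop-seq to describe which cell types the tissue holds. The mesenchyme is the connective tissue beneath the intestinal epithelium. The 5 collections held 2139 barcodes (1A), 1660 (1B), 1614 (2A), 1190 (2B) and 1332 (2C). Their total UMI counts were 3345732, 2756653, 2027029, 1636550 and 1763871. Retained cells numbered 1727, 1305, 1128, 860 and 965, with medians of 1319, 1456, 1226.5, 1376.5 and 1316 UMIs per cell. Over all retained cells the medians were 1330 UMIs and 757 genes, so a gene of 100 CPM gave a UMI in only some of the cells that held it, and comparisons rest on sums over cells.

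Fibroblast-like cells made up 52.2% ± 6.01 of the retained cells (mean ± SD of the 2 biological replicates). They were 1454 of 3032 cells in replicate 1 (47.96%, 95% interval 46.2 to 49.8%) and 1667 of 2953 in replicate 2 (56.45%, 54.6 to 58.2%), and the 5 collections ranged from 47.4 to 57.7%. The next largest classes were blood endothelial-like cells (9.62% ± 1.83), which carried Flt1, Plvap and Kdr, macrophage-like cells (7.92% ± 0.0885; C1qa, Csf1r, Mrc1) and cells like T, natural killer or innate lymphoid cells (6.50% ± 1.49; Cd3e, Trbc2, Il7r). Enteric glia-like cells (4.98% ± 0.191; Sox10, Gfap), pericyte-like cells (4.13% ± 0.183; Rgs5, Kcnj8), smooth muscle-like cells (3.98% ± 0.169; Actg2, Lmod1), B cell-like cells (3.79% ± 2.39; Ms4a1, Cd79a), lymphatic endothelial-like cells (2.78% ± 0.288; Lyve1, Prox1) and dendritic cell-like cells (2.07% ± 0.387; Flt3, Ccr7) followed. Plasma cell-like (42 cells), enteric neuron-like (27) and epithelial-like cells (22) were too few to test. A cluster of 31 cells led by the mitotic genes Cenpf and Top2a stayed unnamed.

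The shares depend on which barcodes were kept. With no limit on mitochondrial UMIs, an alternative chosen after seeing the data, smooth muscle-like cells were 514 cells or 7.74%, against 238 cells or 3.98% at a limit of 10%. No cluster was named for interstitial cells of Cajal. UMIs of at least 3 of their markers were in 92 cells (1.54%), but fibroblast clusters 2 and 4 also carried some of these markers. Of 2 chosen after their values were seen, Gja1 was at 598 to 774 CPM in cluster 2 and 412.5 to 413 CPM in cluster 4, against 104 to 125 CPM in cluster 1, and Kit was at 0 to 7.37 CPM in the 4 clusters. No retained cell had at least 3 neutrophil or mast cell markers, of which the retained cells held 156 and 57 UMIs; at this depth that sets no limit on the shares of these cells.

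**Figure D1:**
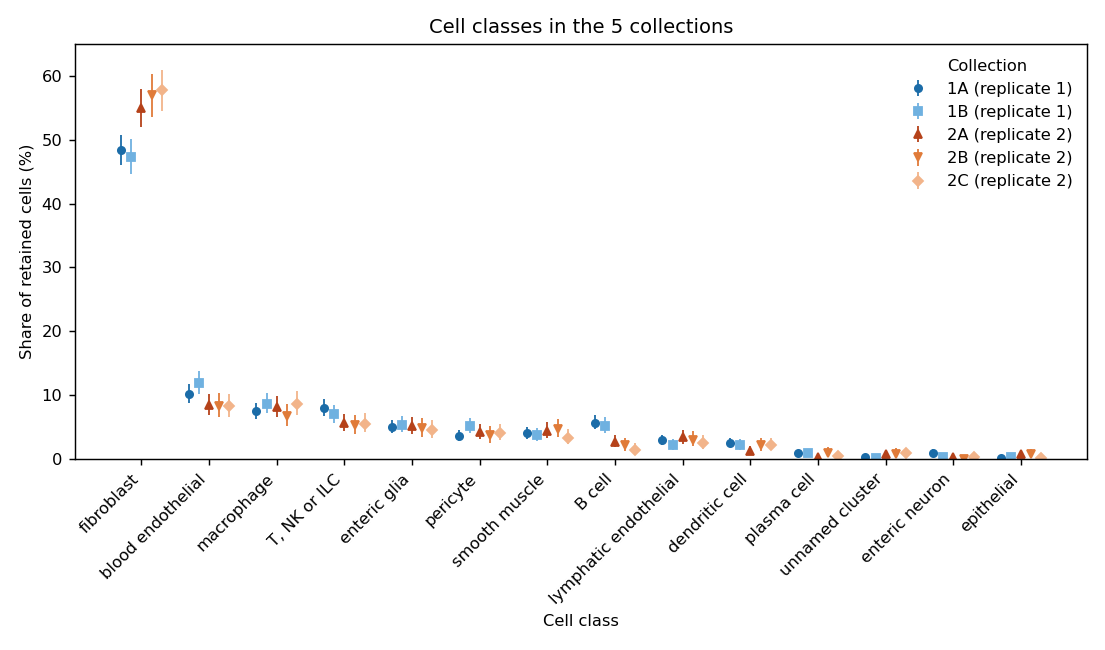
Share of retained cells in percent (vertical axis) for each cell class (horizontal axis) in the 5 collections; points are shares, bars are exact 95% binomial intervals, and colours separate the collections of biological replicates 1 and 2. Fibroblast-like cells ranged from 47.4 to 57.7% over the collections, and B cell-like cells from 1.45 to 5.67%.

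The first comparison asked which secreted signals, matrix genes and lineage genes each of the 10 tested cell classes expressed above the others. In fibroblast-like cells, 84 of the 115 tested list genes were higher and 8 lower (85 and 8 when adjusted over the list alone). Their sums held 2185524 and 2356285 UMIs, against 73009 to 965941 in the other tested classes. Counts of calls at such unequal depth do not rank the classes. The counts here and below are not set against the share of all tested genes called. Alone they do not show that list genes differed more often than others. All 3 tested Wnt ligands were higher than the mean log level of the other classes. Wnt4 and Wnt5a passed the gene filter through fibroblast-like cells alone, and Wnt11 through dendritic cell-like cells alone. The count is therefore no result for the Wnt family. Wnt4 was at 66.1 ± 8.81 CPM (next highest 6.34 CPM in smooth muscle-like cells, adjusted p = 1.1e-47) and Wnt5a at 78.4 ± 7.35 CPM (next highest 22.3, adjusted p = 8.1e-47). Wnt11, named after its value was seen, was at 8.44 ± 2.94 CPM (adjusted p = 0.0027), far below the 102 CPM of dendritic cell-like cells. Of the EGF-family ligands, which drive epithelial growth, Nrg1 stood at 180.2 ± 62.8 CPM (log2 fold change 4.93 ± 0.20, adjusted p = 1.2e-134) and Ereg at 436 ± 49.3 CPM (4.11 ± 0.13, adjusted p = 4.3e-201), while Hbegf was lower at 75.2 ± 6.18 CPM (-0.52 ± 0.17, adjusted p = 0.0048).

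Pdgfra, a receptor widely used to mark fibroblasts, was at 315 ± 24.2 CPM in fibroblast-like cells and at most 25.4 CPM in any other tested class (log2 fold change 4.95 ± 0.16, adjusted p = 2.3e-198). All 3 tested BMP ligands were higher, with Bmp5 at 255 ± 2.94 CPM (4.08 ± 0.16). Of 37 other growth factors, 27 were higher, 2 lower and 8 did not pass. Examples are Fgf7, a growth factor for epithelia, at 176 ± 30.2 CPM, Fgf9 at 62.2 ± 2.68 CPM and Fgf10 at 55.7 ± 16.7 CPM. Of 26 chemokines and cytokines, 17 were higher, among them the B cell attractant Cxcl13 at 80.6 ± 10.2 CPM (next highest 8.03), and 3 lower, including Il1b at 14.5 ± 2.34 CPM. Higher calls did not always mean the highest level: Ccl11 was at 108 ± 16.7 CPM in fibroblast-like cells and 189.6 CPM in pericyte-like cells. Of 16 basement membrane genes 14 were higher.

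In blood endothelial-like cells, 38 list genes were higher and 22 lower (38 and 22 adjusted over the list alone). Dll4, a Notch ligand of arteries and sprouting vessels, was at 343 ± 25.8 CPM (next highest 97.2 in lymphatic endothelial-like cells, adjusted p = 1.9e-132), the vasoconstrictor Edn1 at 406 ± 118 CPM (log2 fold change 5.92 ± 0.20, adjusted p = 1.4e-193) and Inhbb at 124 ± 0.116 CPM (next highest 5). The KIT ligand Kitl was at 417 ± 16.9 CPM (3.31 ± 0.15). In lymphatic endothelial-like cells, 30 list genes were higher and 19 lower (31 and 22 adjusted over the list alone). The lymphocyte survival factor Il7 was at 292 ± 11.2 CPM against at most 15.8 CPM elsewhere (adjusted p = 5.3e-76), the guidance factor Ntn1 at 470.3 ± 24.2 CPM (log2 fold change 5.30 ± 0.25, adjusted p = 2.9e-96) and Gas6 at 753 ± 58 CPM (4.38 ± 0.19, adjusted p = 3.1e-118). The Wnt potentiator Rspo3 was higher there at 117 ± 18.2 CPM (next highest 54.2 in smooth muscle-like cells, adjusted p = 3.2e-25).

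In smooth muscle-like cells, 50 list genes were higher and 12 lower (52 and 12 adjusted over the list alone). All 6 tested BMP antagonists and all 5 tested Hedgehog pathway genes were higher, although Chrdl2 passed the gene filter through this class alone. Hhip, a Hedgehog target that binds the ligands, reached 1268 ± 59.1 CPM (log2 fold change 7.67 ± 0.22, adjusted p = 3.8e-263, next highest 40.6 CPM), Gli1 117 ± 21.3 CPM (adjusted p = 4.6e-17) and the BMP antagonist Chrdl2 66.6 ± 3.82 CPM (adjusted p = 2.4e-14, next highest 2.67 CPM). In pericyte-like cells, 36 list genes were higher and 6 lower (39 and 8 adjusted over the list alone), with the neurotrophin Bdnf at 74.5 ± 11.8 CPM (adjusted p = 7.2e-12). In enteric glia-like cells, 49 list genes were higher and 8 lower (50 and 9 adjusted over the list alone). All 4 tested Wnt antagonists were higher, among them Sfrp1 at 1721 ± 32.6 CPM (4.60 ± 0.12), Sostdc1 at 312 ± 68.1 CPM (next highest 6.34) and Sfrp5 at 263 ± 4.37 CPM (next highest 2.94, adjusted p = 1.2e-89). Sostdc1 and Sfrp5 passed the gene filter through glia-like cells alone. Hbegf was at 1926 ± 51.7 CPM in glia-like cells (4.54 ± 0.12) and at 625 CPM in blood endothelial-like cells, the next highest class. Immediate-early and heat-shock genes, which respond to tissue dissociation, made up 5.01% ± 0.354 of the UMIs of glia-like cells. The share was 3.20% ± 0.0708 in fibroblast-like, 3.04% ± 0.137 in pericyte-like, 2.79% ± 0.0847 in smooth muscle-like, 2.68% ± 0.00889 in blood endothelial-like and 2.27% ± 0.0793 in lymphatic endothelial-like cells. It ranged from 0.485 to 1.14% in the 4 immune classes tested.

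Among immune classes, macrophage-like cells had 17 of 26 chemokines and cytokines higher and 1 lower. Cxcl2, a neutrophil attractant, was at 6987 ± 687 CPM (log2 fold change 4.86 ± 0.08), Ccl3 at 1862 ± 30.5 CPM (5.62 ± 0.11) and Tnf at 407 ± 58.9 CPM (next highest 82.1, adjusted p = 9.7e-160). Il1b was highest in dendritic cell-like cells at 2752 ± 843 CPM, against 823 CPM in macrophage-like cells, and Wnt11 stood there at 102 ± 22.4 CPM (next highest 9.78, adjusted p = 1.1e-19). Cells like T, natural killer or innate lymphoid cells carried the amphiregulin gene Areg at 215 ± 111 CPM (3.66 ± 0.28, adjusted p = 2.0e-36), Tnfsf11 (RANKL) at 217 ± 52.2 CPM and Npnt at 172 ± 2.32 CPM. In B cell-like cells 2 list genes were higher than the mean log level of the other classes. Tgfb1 was at 235 ± 16 CPM (next highest 216 in macrophage-like cells, adjusted p = 2.8e-10). Ccl4 was at 75.3 ± 48.4 CPM, from 23 and 3 UMIs (adjusted p = 8.9e-05), far below the 1103 CPM of macrophage-like cells. The counts of higher and lower list genes were 30 and 26 in macrophage-like, 16 and 25 in dendritic cell-like, 11 and 41 in T, natural killer or innate lymphoid-like and 2 and 37 in B cell-like cells (30 and 26, 16 and 25, 11 and 45, and 2 and 37 adjusted over the list alone).

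Over the classes, 38 pairs of list and class passed camera with the preset correlation and 7 of them held with an estimated correlation. These 7 were other growth factors up in fibroblast-like cells (adjusted p = 0.037 with an estimated correlation) and lineage genes up in the same class (adjusted p = 0.037), BMP antagonists and Hedgehog genes up in smooth muscle-like cells (both adjusted p = 0.037), chemokines and cytokines up in macrophage-like cells (adjusted p = 0.037), and other growth factors down in the T, natural killer or innate lymphoid class (adjusted p = 0.037) and in B cell-like cells (adjusted p = 0.044). The list calls for Wnt antagonists in glia-like cells (adjusted p = 0.118 with an estimated correlation) and for Wnt ligands (adjusted p = 0.152), BMP ligands (adjusted p = 0.0521), chemokines and cytokines (adjusted p = 0.0756) and basement membrane genes (adjusted p = 0.0521) in fibroblast-like cells did not hold. Summing UMIs per collection lowered the higher calls in blood endothelial-like cells from 38 to 25 and in pericyte-like cells from 36 to 23.

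The second comparison asked how niche signals were divided among the fibroblast-like cells, which fell into 4 clusters. Cluster 1 held 1517 cells (48.4% ± 3.89 of fibroblast-like cells) and was led by Edil3, Stmn2, C4b and Serpina3n, with the adventitial or submucosal markers Clec3b and Mfap5 raised. Cluster 2 (718 cells, 23.1% ± 2.41) was led by Plau, Saa3, Bcr and Niacr1 and had F3, Ednrb, Tnc and Col6a5 of the subepithelial fibroblast markers raised. Cluster 3 (568 cells, 18.4% ± 4.31) was led by Has1, Pcolce2, Gfpt2 and Ebf1 and had the adventitial or submucosal markers Mfap5, C3, Has1, Cd55, Ugdh and Fbn1 and the lamina propria markers Scara5 and Col14a1 raised. Cluster 4 (318 cells, 10.1% ± 2.84) was led by Rbp4, Tmem158, Aldh1a1 and Sox6, with the subepithelial markers Sox6, Ednrb and Procr, the lamina propria marker Ptgis and the smooth muscle markers Myh11, Acta2, Tagln and Myl9 raised. Only raised markers are listed here, and other members of the same lists went the other way. The lamina propria marker Adamdec1 was at 96 to 193.7 CPM in cluster 3, against 4067 to 4869 CPM in clusters 1, 2 and 4. The adventitial or submucosal marker Has1 was at 52.0 to 96.5 CPM in cluster 1, against 2182 to 2366 CPM in cluster 3. The raised markers alone therefore do not assign clusters 1 and 3 to a kind of fibroblast. Median depths were 1145, 1653, 1588.5 and 984 UMIs per cell in clusters 1 to 4.

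In cluster 1, 35 of 131 tested list genes were higher than in the other fibroblast clusters and 31 lower (39 and 34 adjusted over the list alone). Its raised genes included the Wnt ligand Wnt2b at 78.9 ± 7.85 CPM (next highest 17.6 CPM in cluster 4, log2 fold change 2.20 ± 0.27, adjusted p = 6.6e-12) and the BMP antagonist Grem1 at 355 ± 3.37 CPM (2.66 ± 0.19, adjusted p = 6.0e-27), which was as abundant in cluster 3 (346 CPM). Of 7 Wnt antagonists 4 were higher and none lower, with Sfrp1 at 1069 ± 169 CPM (1.99 ± 0.11, adjusted p = 4.1e-36), Sfrp2 at 29.5 ± 8.2 CPM (next highest 5.73, adjusted p = 4.2e-08) and Frzb at 24.5 ± 0.505 CPM. The B cell survival factor Tnfsf13b (BAFF) was at 89.8 ± 19.96 CPM (3.39 ± 0.31, adjusted p = 5.9e-19), the leptin receptor Lepr at 151 ± 8.85 CPM (2.43 ± 0.22) and the basement membrane collagen Col15a1 at 461 ± 81.7 CPM (2.01 ± 0.13). Bmp2 was lower at 90.9 ± 1.39 CPM (-2.23 ± 0.14, adjusted p = 6.4e-31), as were Nrg1 at 13.8 ± 2.79 CPM (-2.56 ± 0.39) and Fgf9 at 1.65 ± 1.02 CPM (-6.06 ± 0.39). Of 5 EGF-family ligands none was higher and 4 were lower. With DESeq2 the higher calls fell to 18.

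In cluster 2, 53 list genes were higher and 16 lower (55 and 19 adjusted over the list alone). Of the 5 tested EGF-family ligands 4 were higher, with Nrg1 at 577 ± 137 CPM (next highest 132 CPM in cluster 4, log2 fold change 4.86 ± 0.17, adjusted p = 5.4e-62), Ereg at 1187 ± 108 CPM (3.43 ± 0.12, adjusted p = 2.1e-63) and Areg at 252 ± 24.3 CPM (3.29 ± 0.18, adjusted p = 2.7e-37). Ptgs2, the inducible enzyme of prostaglandin synthesis, was at 1905 ± 299 CPM against at most 323 CPM in the other clusters (3.32 ± 0.10, adjusted p = 8.8e-68). Of 25 chemokines and cytokines 14 were higher and 1 lower, including Cxcl10 at 877 ± 178 CPM (2.46 ± 0.12), Cxcl2 at 834 ± 150.1 CPM (2.81 ± 0.13) and Cxcl9 at 62 ± 8.7 CPM (4.16 ± 0.41). Bmp2 was highest in this cluster at 689 ± 41.3 CPM (next highest 387 CPM, 2.02 ± 0.11, adjusted p = 5.8e-38). The Notch ligand Dll1 was at 130.1 ± 35.9 CPM (3.26 ± 0.26) and the neurotrophic factor Gdnf at 154 ± 13 CPM (3.61 ± 0.24). Cd34 at 76.7 ± 23.9 CPM (-1.45 ± 0.22), Igf1 at 87.3 ± 8.18 CPM (-1.34 ± 0.17) and Lepr at 14 ± 5.75 CPM (-1.75 ± 0.41) were lower. Immediate-early and heat-shock genes made up 3.76% ± 0.283 of the UMIs of cluster 2, against 2.93% ± 0.0160, 3.16% ± 0.0614 and 2.77% ± 0.502 in clusters 1, 3 and 4. The lower calls fell to 8 with DESeq2 and rose to 39 with a minimum of 200 genes per cell.

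In cluster 3, 45 list genes were higher and 41 lower (45 and 49 adjusted over the list alone). Of 11 lineage genes 8 were higher and 1 lower. Pi16, a marker of adventitial fibroblasts, was at 598 ± 243 CPM (next highest 19.4, adjusted p = 6.1e-67) and Cd81 at 279 ± 21.1 CPM (log2 fold change 3.05 ± 0.18, adjusted p = 1.2e-34). Cd34 was at 659 ± 5.68 CPM (next highest 470.7 and 482.5 CPM in cluster 1, 2.58 ± 0.14, adjusted p = 3.2e-39). The atypical chemokine receptor Ackr4 was at 87.5 ± 4.15 CPM (next highest 1.06, adjusted p = 2.7e-27). Rspo3 was highest here at 65.5 ± 17 CPM (3.33 ± 0.39, adjusted p = 4.0e-13), as were the Hedgehog co-receptor Gas1 at 182 ± 14.6 CPM (5.28 ± 0.29) and the alarmin Il33 at 134 ± 46.3 CPM (next highest 20.7, adjusted p = 1.7e-28). The monocyte attractants Ccl2 and Ccl7 were at 946 ± 104 CPM (3.57 ± 0.15) and 551 ± 165 CPM (3.42 ± 0.15). Of 6 BMP ligands none was higher and 4 were lower, with Bmp4 at 200.2 ± 6.45 CPM (-2.27 ± 0.14, adjusted p = 1.9e-34), Bmp5 at 15.7 ± 9.21 CPM (-4.49 ± 0.25, adjusted p = 2.2e-38) and Bmp7 at 5.92 ± 2.07 CPM (-3.41 ± 0.42). Wnt4 at 3.15 ± 1.84 CPM (-4.60 ± 0.48) and Nrg1 at 6.65 ± 6.26 CPM (-3.67 ± 0.40) were also lower.

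In cluster 4, 29 list genes were higher and 29 lower (30 and 34 adjusted over the list alone). Of 6 BMP ligands 5 were higher and none lower, with Bmp5 at 745 ± 103 CPM (next highest 447 CPM in cluster 2, log2 fold change 2.59 ± 0.16, adjusted p = 1.5e-31). Bmp4 was at 1485 ± 224 CPM (next highest 1157 and 1237 CPM in cluster 1, 1.21 ± 0.12, adjusted p = 1.1e-17). Bmp7 was at 173 ± 78.2 CPM (2.66 ± 0.29, adjusted p = 2.0e-14) and Bmp3 at 71.2 ± 17.4 CPM (4.08 ± 0.56). Wnt5a, a non-canonical Wnt ligand, was at 248 ± 28 CPM (1.88 ± 0.22, adjusted p = 4.8e-13) and the Wnt antagonist Wif1 at 63.2 ± 14.8 CPM (next highest 2.26, adjusted p = 2.2e-10). Pdgfra was highest in this cluster at 597 ± 0.548 CPM (0.81 ± 0.14, adjusted p = 9.1e-07). Foxl1, a transcription factor of subepithelial telocytes, was at 35.2 ± 18.5 CPM (2.82 ± 0.69, adjusted p = 8.7e-04), from 3 and 11 UMIs in the 2 replicates. The basement membrane collagens Col4a5 and Col4a6 were at 375 ± 32.8 CPM (2.75 ± 0.20) and 131 ± 23.4 CPM (3.81 ± 0.39). Grem1 was lower at 6.59 ± 9.32 CPM (-4.60 ± 0.47, adjusted p = 4.4e-16), as was Ccl2 at 14 ± 1.1 CPM (-4.87 ± 0.36). Pi16 had no UMI in cluster 4, which made it at least 72.5-fold lower than in cluster 3 by a floor of 3 counts over the cluster. The cluster had no counterpart with a minimum of 200 genes per cell or in the alternative with split UMIs, and DESeq2 called 19 lower genes.

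Gli1 did not pass in any of the 4 clusters, with CPM in the 8 sums from 30.8 to 123. Rspo1 was at 3.71 to 13.3 CPM in the 8 sums and was not tested. By camera with the preset correlation, EGF-family ligands were up in cluster 2 (adjusted p = 0.0037) and down in cluster 1 (0.0027) and cluster 3 (0.039). BMP ligands were up in cluster 4 (0.0027) and down in cluster 3 (0.0027), and chemokines and cytokines up in cluster 2 (0.0027) and down in cluster 4 (0.025). Lineage genes were up in cluster 3 (0.0027) and down in cluster 2 (0.041) and cluster 4 (0.0092). None of these 10 calls held with an estimated correlation, where the adjusted p lay between 0.28 and 0.41; 6 of the 10 had an unadjusted p under 0.05 there.

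**Figure D2:**
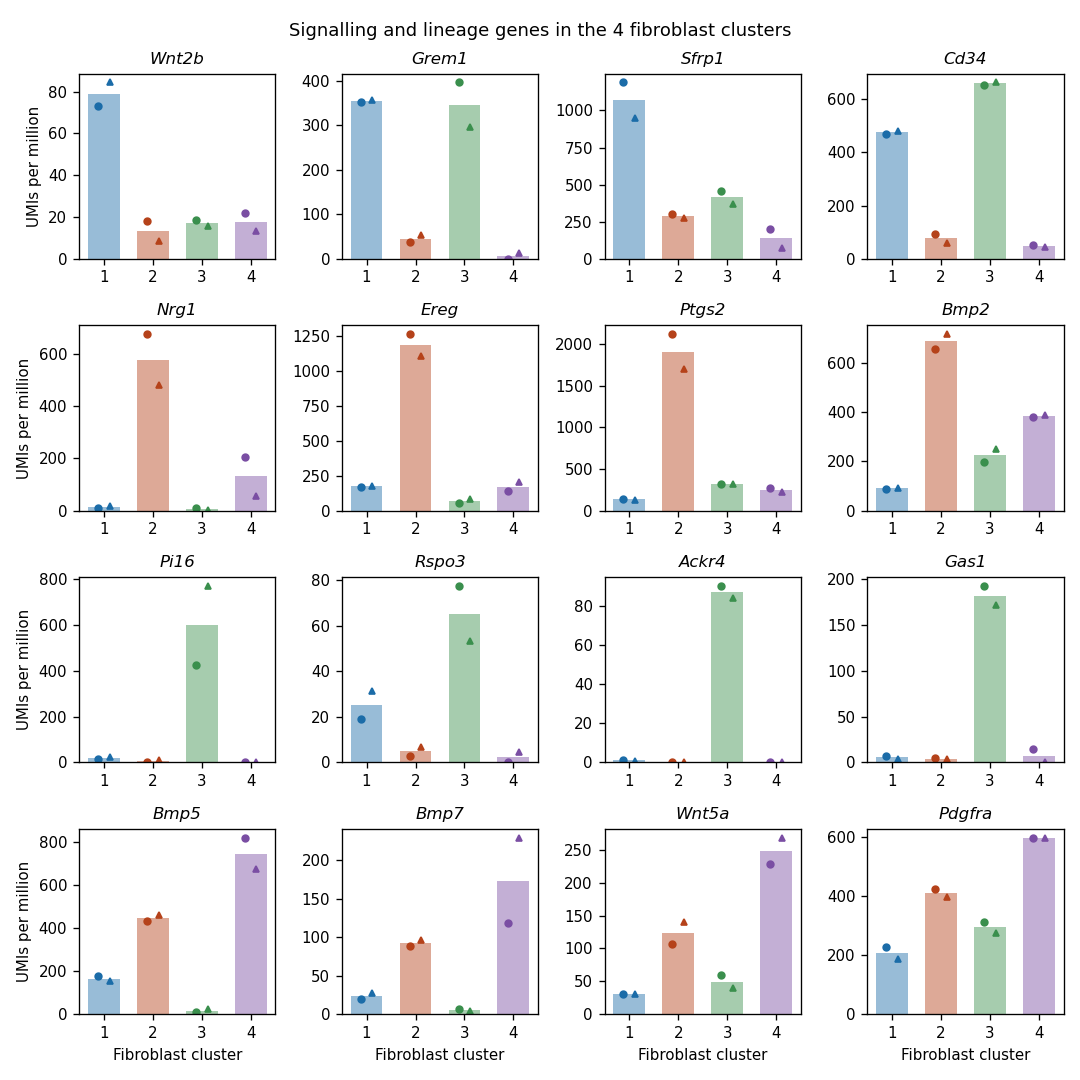
CPM (vertical axes, each from 0) of 16 signalling and lineage genes in the 4 fibroblast clusters (horizontal axes); bars are means of the 2 biological replicates, circles replicate 1 and triangles replicate 2. Nrg1, Ereg, Ptgs2 and Bmp2 were highest in cluster 2, Pi16, Rspo3, Ackr4 and Gas1 in cluster 3, and Bmp5, Bmp7, Wnt5a and Pdgfra in cluster 4.

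The last comparison asked how closely the 2 biological replicates matched. Over 20025 genes, the CPM of all retained cells correlated across genes with Pearson's r = 0.984 and Spearman's rho = 0.969 on the log2(CPM+1) scale. Genes are not independent replicates. Within single tested classes r was lower, from 0.626 in pericyte-like, 0.670 in smooth muscle-like and 0.675 in B cell-like cells to 0.977 in fibroblast-like cells. Pairs of collections were compared over all 7935 deposited barcodes, including those left out elsewhere, and correlated with r = 0.962 to 0.979. The r was 0.979 within replicate 1, 0.962 to 0.966 within replicate 2 and 0.967 to 0.974 between replicates, so it did not separate the replicates. The chi-square per degree of freedom was 2.19 to 3.43 for pairs within a replicate and 3.73 to 4.56 for pairs between replicates. That value counts each UMI as an independent draw, so it exceeds 1 wherever cells differ in type. In fibroblast-like cells, 1599 genes reached 100 CPM in a replicate, and none differed by more than 2-fold between the replicates. In 38.0% of them, against 20% by chance for 2 against 3 collections, the collections of the 2 replicates did not overlap (335 genes higher in replicate 1 and 272 in replicate 2). The transcription factor Runx1 had the highest ratio towards replicate 1 at 108 against 54.7 CPM, followed by Fas (107 against 59.4), Ptpn1 (131 against 77.2), Nrg1 (225 against 136), Plau (239 against 152), Nfkb2, Nfkb1, Gm26669, Niacr1 and Myc. Ctgf (Ccn2) had the highest ratio towards replicate 2 at 252 against 152 CPM, followed by Gm10269 (640.4 against 389), Rbp4 (157 against 96.1), Ndufa11, Acta2, Tspan4, Shoc2, Ackr3, Arpp19 and Ccl8. The mix of fibroblast clusters also differed between the replicates, with 24.8 and 21.4% of cells in cluster 2, 21.5 and 15.4% in cluster 3 and 8.05 and 12.1% in cluster 4. Nrg1, Plau and Niacr1 were among the genes of cluster 2 and Rbp4 and Acta2 among those of cluster 4, so these ratios are not levels within 1 kind of fibroblast. With 2 replicates no test between them was possible.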

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

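All tests of explanations in this part were chosen after the result was seen, except the test of dissociation genes and the test of pericyte RNA. The data hold 1 untreated group, so no biological explanation was tested for any of the 3 patterns.

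The first pattern is the higher level of the EGF-family ligands Nrg1, Ereg and Areg and of Ptgs2 in fibroblast cluster 2, where immediate-early genes are also higher; Hbegf passed there too, at 96.6 CPM, but was as abundant in cluster 3 (91.4 CPM). In the third of cells with the lowest immediate-early share, the median log2 fold of the 5 genes against other fibroblast-like cells was 4.64. It was 4.95 and 4.32 in replicates 1 and 2, against 3.11 in all cells. This argues against the summed immediate-early share as the source, except for Hbegf, at -0.22 from 4 UMIs in replicate 2. The share was still higher in the 84 and 49 cluster 2 cells used (1.64 and 1.87%) than in the other cells (1.19 and 1.28%). It also does not follow every member. Ier3 was at 3186 to 3216 CPM in cluster 2 and 540 to 1024 CPM in clusters 1, 3 and 4. Fos was at 4075 to 4660 CPM in cluster 2 and 5607 to 5816 CPM in cluster 1. The immediate-early genes had been left in the clustering, and Ier3 was among the leading genes of cluster 2. A response of single members such as Ier3 stays open. RNA from another class would need 885% of the level of the richest other class for the median of Nrg1, Ereg and Ptgs2 (329.65% for Ereg in replicate 2, the lowest of the 3), more than admixture can give, and 119.89% for Areg (169.5% and 70.3% in replicates 1 and 2), where markers of T, natural killer or innate lymphoid cells stood at 0.0349%. Hbegf would need 1.40% of the glial level, while glial markers in cluster 2 stood at -0.0947%. A response to dissociation that raises Ptgs2 and Ereg without the immediate-early genes of the list used here stays open.

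The second pattern is the smooth muscle markers Myh11, Acta2, Tagln and Myl9 in fibroblast cluster 4, at a median of 7.96% of the smooth muscle level. The 9 other genes abundant in smooth muscle-like cells, chosen without cluster 4, stood at a median of 3.74% (1.80% and 5.68% in replicates 1 and 2). Of these, 5 were at no less than 50% of the level of the raised markers, among them Mylk at 9.27%, while Actg2, Lmod1, Hhip and Cnn1 stood at -0.761 to 0.721%, so RNA from smooth muscle cells stays open. Pericyte markers stood at 0.567% of the pericyte level, where 15.9% would be needed, although Kcnj8, Abcc9, Cspg4 and Cox4i2 stood at 4.07 to 21.2%. The pericyte median argues against pericyte RNA, in doublets or free in the suspension, as the whole source.

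The third pattern is the B cell-like share of 5.47% in replicate 1 and 2.10% in replicate 2. With a minimum of 200 genes the ratio of cells with at least 2 B cell markers was 2.91, which argues against the minimum of 300 genes as the source. With barcodes thinned to 500 UMIs it was 3.22, but this left out 836 of 3799 barcodes of replicate 1 and 1277 of 4136 of replicate 2, so depth stays open. A smaller fibroblast share would raise every other class alike, but the B cell ratio was 2.46 times the median of the 8 others, which ranged from 0.863 to 1.39. How much lymphoid tissue each dissection held stays open.

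Collection 2C had 0.0421% of UMIs in proliferation genes, below the 0.0478 to 0.0496% of the other 4 collections; of 26 measures 1 stood this far apart, where 1.3 were expected by chance. Among cells used in no comparison, enteric neuron-like cells were 0.451% (0.258% without collection 1A, which held 16 of the 27), plasma cell-like cells 0.702%, epithelial-like cells 0.368% and the unnamed proliferating cluster 0.518% of the retained cells. Each was a cluster already, so a share above the 0.0501% that a count of 0 allows was fixed in advance and supports nothing. Barcodes with under 300 genes held 3.04 times the CPM of smooth muscle markers, 3.31 times that of neutrophil markers, 2.32 times that of epithelial markers and 317 times that of erythroid markers found in retained cells. Barcodes with over 10% mitochondrial UMIs held 21.02 times the CPM of smooth muscle markers, 5.60 times that of pericyte markers, 3.35 times that of mast cell markers and 4.18 times that of epithelial markers found in retained cells.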

How the results depend on the processing

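Removing the cells with the highest doublet scores and lifting the mitochondrial limit were chosen after seeing the data; all other alternatives were fixed before. Of 606 values of the main results under the alternatives, 571 kept their side. Of 7565 values of named genes, 7148 kept their call, 388 lost it, 24 gained it and 5 changed direction. These include the values without biological replicate 1 or 2, which have no test and were scored by sign alone. For genes named by the rule that sign was already required, so those values could not change. Settings under which a gene or cluster was not tested gave no value and are not in these totals. Cluster 4 is such a case with a minimum of 200 genes and with split UMIs. With a minimum of 200 genes, Bmp5 in cluster 1 turned to 0.84 and Bmp3 in cluster 2 to 2.21. With split UMIs, Bmp5 in cluster 1 turned to 1.03, Bmp7 to 1.30 and Col4a6 to 1.81. Cluster 4 had no counterpart under either setting. Cluster 2 then held 1112 cells with a minimum of 200 genes, and clusters 1 and 2 held 1698 and 922 with split UMIs, against 1517 in cluster 1 and 718 in cluster 2. Of 204 class shares under the alternatives, 23 moved beyond their spread. Plasma cell-like cells were 1.17% with no doublets removed and 1.24% at resolution 0.6, enteric neuron-like cells 0.835% with split UMIs, and epithelial-like cells 0.572% with no mitochondrial limit and without a cluster with split UMIs. The unnamed proliferating cells formed no cluster with no doublets removed, at resolution 0.6 or with split UMIs.

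Split UMIs halve the depth for the test and also change the clusters. There, higher calls in blood endothelial-like cells were 25 (38 with all UMIs) and in dendritic cell-like cells 10 (16). Lower calls were 10 in blood endothelial-like (22), 11 in lymphatic endothelial-like (19), 2 in pericyte-like (6), 6 in smooth muscle-like (12), 0 in glia-like (8), 13 in macrophage-like (26) and 26 in T, natural killer or innate lymphoid-like cells (41), and 28 in fibroblast cluster 2 (16). Sums per collection gave 25 higher calls in blood endothelial-like, 23 in pericyte-like (36) and 7 in T, natural killer or innate lymphoid-like cells (11). Lower calls in glia-like cells were 5 with a minimum of 500 genes, 4 without the highest doublet scores, 1 with DESeq2 and 5 with RLE factors. A minimum of 500 genes left 1 higher gene in B cell-like cells (2), and a minimum of 200 genes gave 39 lower calls in cluster 2. With no gene filter, 129 genes were higher in fibroblast-like cells (84). DESeq2 gave 18 higher calls in cluster 1 (35), 8 lower in cluster 2 (16) and 19 lower in cluster 4 (29). List tests passing numbered 7 with an estimated correlation and 86 with fry for classes (38), and 0 and 26 for clusters (10). The replicate correlation was 0.991 on log2(CPM+10) and 0.973 above 10 CPM (0.984). The cause was not tested for these changes.

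Leaving out 1 collection at a time gave 5 to 8 lower calls in fibroblast-like, 14 to 20 in blood endothelial-like, 11 to 19 in lymphatic endothelial-like, 3 to 8 in pericyte-like and 3 to 8 in glia-like cells. Without the replicate block, 331 of 342 named-gene results kept their call, 11 lost it and 0 changed direction, and no count of calls moved by over 1.5 times.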

Other observations

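The genes named here were chosen after their values were seen, and no explanation was tested. A blood endothelial-like cluster of 36 cells was led by the adhesion molecules Selp, Sele and Madcam1, which postcapillary venules carry, and by Darc (Ackr1). A cluster of 88 cells among the T, natural killer or innate lymphoid class was led by Il5, Calca and Gata3, genes of group 2 innate lymphoid and T helper 2 cells. Another of 302 cells was led by Il22, a cytokine that acts on the epithelium, and Trbc2. The 27 enteric neuron-like cells were led by Snhg11, Elavl4 and Nos1, the enzyme of nitrergic neurons.

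Xist, expressed from the inactive X chromosome, was at 424 to 497 CPM in the 5 collections, and Y-linked genes had 0 UMIs. Collections 2A and 2B shared 7 cell barcodes, where 0.114 were expected by chance, and 5 of these were retained in both with the same class. Barcode pairs that differed in the last base numbered 15, 19, 16, 0 and 6 in the 5 collections, where 0.409, 0.246, 0.233, 0.127 and 0.159 were expected.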
